A study of Saccharomyces cerevisiae with 32 samples.

How the data were processed

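Total RNA of 32 samples of 1 continuous culture was measured on Affymetrix Yeast Genome 2.0 arrays, 1 array per sample, with 5 µg of labelled cRNA hybridised per array per the labels. The deposited values are linear probe set intensities; the submitters' processing notes name GCOS, and its version, algorithm and scaling are not given in the sources used here. The median intensity of the S. cerevisiae probe sets differed between arrays by up to 0.70 on the log2 scale, so no common scaling was visible in the deposited values. Correlations between arrays lay between 0.663 and 0.997, and 0 pairs of columns were identical.

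Of 10928 probe sets, 5498 were assigned to 1 S. cerevisiae gene each and 1747 to S. pombe, of which 1 named several genes. A further 3470 had no name and 213 were controls without a gene. Gene names came from the array annotation and the S. cerevisiae R64 table, which was used for names alone and not for coordinates. Signals were taken to log2 after adding 1.9, the 10th percentile of all values. By a rule fixed beforehand, arrays were quantile normalized over the S. cerevisiae probe sets because their medians spanned more than 0.5. The brightest probe set stood for each of 5449 genes, and 5378 genes with a mean above the 95th percentile of the S. pombe probe sets (4.45 on the log2 scale) were tested; 110 of them were read from probe sets that can match more than 1 gene.

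Calculations used R 4.3.3 and limma 3.58.1. Each gene was fitted with the cosine and sine of the phase angle of the labels, and a moderated F test with Benjamini-Hochberg adjusted p under 0.05 called genes that varied; the fitted range is the difference between peak and trough of the curve. A fit with 2 harmonics tested the second harmonic. The first 3 samples were compared with the last 3 by limma. For 31 gene lists (991 genes found, 2 entries not matched) the mean log2 level per array was fitted in the same way, with 100000 permutations of the phases, jackknife errors over the 32 samples and over 8 blocks of 4 neighbouring samples, and 10000 random lists matched on size and expression. Peak phases of 11 pairs of lists were compared with jackknife intervals of 95%.

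Genes named in the text were chosen by a fixed rule. They are the 2 genes with the largest range in each of 8 windows of 45°, up to 3 varying members with the largest range of each list, the 10 common reference genes, the 6 genes with the largest second harmonic among those where it exceeds the first, and the 6 with the smallest adjusted p between the first and last 3 samples. Other genes are named with a statement that they were chosen afterwards, or as members of a list that did not pass.

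The tests were tried on simulated data with 5378 genes. With independent noise the fit called 84.0% of genes with a range of 0.5 and 100% of genes with ranges of 1, 2 and 4, and 0.212% of unchanged genes. With noise of the observed autocorrelation it called 47.0% of unchanged genes, and after whitening 0.135%, while 50.0%, 84.0%, 100% and 100% of the changed genes were called. The comparison of 3 with 3 samples called 88.0% of genes that differed by 1 on the log2 scale with independent noise, and 15.8% of unchanged genes with autocorrelated noise. These simulated genes were flat over the cycle, whereas each real set of 3 samples also holds its course. The 88.0% is therefore not the power of the comparison in the real data. Fitted peaks from odd and even time points differed by a median of 2.13° over the 1574 genes with at least 2-fold range.

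Results were also computed, where each choice applies, with the deposited values without scaling, no filter or a stricter filter (5.16), other pseudocounts, the mean of a gene's probe sets, linear time or the array running number as an added term, whitening, odd or even time points alone, leaving out the last 3 samples, 2 harmonics, list members scaled to SD 1, matched phase as a block, and leaving out each of the 6 compared samples. Scaling by the poly-A controls, scaling by the array median, leaving out the 5 samples of lowest poly-A signal and the block jackknife were added after seeing the data. Unnamed, control and S. pombe probe sets were left out of the tests of genes because they name no S. cerevisiae gene.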

Results

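The data were 32 expression arrays of the haploid budding yeast strain CEN.PK113-7D, a laboratory strain used in physiology work. The strain was grown in continuous culture at 30 °C and pH 4.0, under conditions in which the dissolved oxygen of the medium oscillated with a period of about 2 h. The dilution rate was given as 0.06 to 0.086 per h for all samples. A sample of 0.5 ml was taken every 4 min from 10.0 h to 12.1 h of the time scale in the labels, and each sample was hybridised to its own array. The labels give every sample a phase angle of the oscillation, which advanced by 12.5° per sample, so that a full turn of 360° took 115 min. Where the angle of 0° lies relative to oxygen consumption is not given in the sources used here. The series forms 1 group with no replicate time points. All samples came from 1 culture, so p-values measure only the spread of these samples around a fitted curve. The median signal of the S. cerevisiae probe sets lay between 1436 and 2340.2 on the 32 arrays, against 5.4 to 9.8 for probe sets of the fission yeast S. pombe on the same arrays, which served as the background. The number of arrays limits the precision of every value below.

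The question posed by the design was which transcripts changed over a cycle of the 2 h oscillation, by how much and at which phase. Genes of ribosome assembly, RNA polymerases I and III and sulfur amino acid synthesis peaked near 0°, and genes of DNA replication peaked near 80°. Mitochondrial ribosomal protein genes and histone genes peaked near 175°, and genes of storage carbohydrates, autophagy, heat shock and peroxisomes between 200° and 230°. Curves with 2 harmonics brought these groups together, with maxima at 146° and 152° for the mitochondrial ribosomal protein and histone lists and at 144°, 146°, 160.0° and 161° for the other 4. Such maxima lay at 27°, 28° and 36° for ribosome biogenesis, RNA polymerases I and III and the sulfur list, and at 70° for DNA replication. With poly-A scaling the mitochondrial ribosomal protein and histone lists peaked at 130.5° and 123°. Of 5378 genes tested, 4910 (91.3%) varied with phase (limma moderated F test of the cosine and sine of phase, Benjamini-Hochberg adjusted p under 0.05) and 468 did not pass. The median fitted peak-to-trough range of the varying genes was 0.70 on the log2 scale. The largest ranges were those of AAH1 (YNL141W), which encodes adenine deaminase, with 5.21 ± 0.43 (SE, n = 32) and a peak at 7.8°, and of the RNA helicase gene DBP2 (YNL112W), with 4.86 ± 0.42 and a peak at 13.4°. Fitted ranges of at least 2-fold were found for 1574 genes (29.3%), of at least 4-fold for 489 and of at least 8-fold for 136. Neighbouring samples were not independent (median lag-1 autocorrelation of the residuals 0.66). In data simulated with that autocorrelation and 5378 genes, the same fit called 47.0% of unchanged genes, against 0.212% with independent noise; after whitening for the autocorrelation it called 0.135% of them, and 3601 of the real genes.

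Peak phases of the single cosine curve were concentrated near 0° and near 200°. These phases can differ from those of the highest levels. The heat shock list, for instance, had its fitted peak at 224° and its maximum at 160° with 2 harmonics. Of the genes with at least 2-fold range, 463 peaked between 0° and 45° and 185 between 315° and 360°, which together with 514 between 180° and 225° made up most of the 1574. The window from 270° to 315° held 5 such genes, that from 90° to 135° held 60, and the remaining windows held 131 (45° to 90°), 94 (135° to 180°) and 122 (225° to 270°). The windows depended on how arrays were scaled. With arrays scaled by the poly-A control transcripts, 42.9% of 2080 genes with at least 2-fold range peaked between 0° and 45° and 10.8% between 180° and 225°, against 29.4% and 32.7% with quantile normalization. The window from 45° to 90° held 29.8% with poly-A scaling against 8.32%. With the deposited values, 20.6% of 1605 genes peaked between 0° and 45°, 35.6% between 180° and 225° and 22.9% between 315° and 360°.

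**Figure D1:**
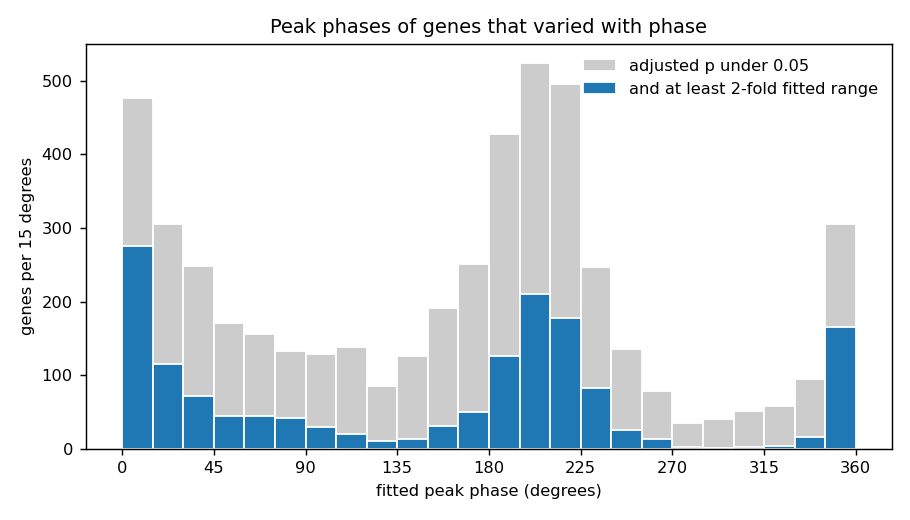
Histogram of the peak phase of the single cosine curve, in degrees, of the 4910 genes that varied with phase (grey) and of the 1574 with at least 2-fold fitted range (blue), in genes per bin, after quantile normalization. This phase can differ from that of the highest sample. The blue bars are highest on both sides of 0° and near 210°, and the window from 270° to 315° holds 5 of these genes; with poly-A scaling the share between 180° and 225° is 10.8% in place of 32.7%.

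The genes with the largest range in each window of 45° came from different processes. TRM11 (YOL124C), encoding the catalytic subunit of a tRNA methyltransferase, had a range of 4.66 ± 0.53 and peaked at 355°, and the methionine permease gene MUP1 (YGR055W) had 4.31 ± 0.41 and peaked at 333°. The S-phase cyclin gene CLB6 (YGR109C) had a range of 3.25 ± 0.22 with a peak at 88.2°, beside the uncharacterised YLR342W-A with 3.18 ± 0.21 at 80.4°. TOS4 (YLR183C) and PLM2 (YDR501W), which encode related forkhead-associated domain proteins, had ranges of 2.84 ± 0.12 and 2.46 ± 0.10 with peaks at 94.8° and 122°. YJR115W and MGA1 (YGR249W) followed at 165° and 157°, with 2.23 ± 0.31 and 2.20 ± 0.39. The lowest signal of MGA1, 15.8, lay near the background, so the size of its range is not exact. GIP2 (YER054C), a regulatory subunit of protein phosphatase in glycogen metabolism, had 4.27 ± 0.58 at 209°, and the plasma membrane heat shock protein gene HSP30 (YCR021C) had 4.16 ± 0.54 at 219°. FAT3 (YKL187C), needed for fatty acid uptake, peaked at 232° with 4.17 ± 0.54, and the catalase gene CTT1 (YGR088W) at 239.9° with 3.60 ± 0.34. In the sparse window after 270°, the cytochrome b5 gene CYB5 (YNL111C) had 1.95 ± 0.25 at 305°. The sporulation gene SPO19 (YPL130W) had a fitted range of 2.78 ± 0.53 at 303°, but its mean of 4.53 lay near the background of 4.45, so the size is not exact. Its levels in the first and last 3 samples were 4.40 and 6.54, and its call was lost after whitening (limma adjusted p = 0.253). The largest limma adjusted p among these 16 genes was 7.45e-05, for SPO19.

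Most profiles were not single sinusoids. AAH1 had its highest signal, 13483, in the last sample, at 23.8°, and its lowest, 184, at 159°, a 72.7-fold difference. TRM11 fell from 4473 at 34.3° to 28.4 at 122°, a 147-fold difference whose size is not exact, since the low signal lay near the background. GIP2 went the other way, from 81.5 at 46.8° to 6798 at 134°. The second harmonic passed its test in 4513 genes (limma moderated F test, adjusted p under 0.05), and a curve with 2 harmonics took the median share of variance explained from 0.605 to 0.844. In 546 of these genes the amplitude of the second harmonic exceeded that of the first. The largest such amplitudes were those of the uncharacterised genes YOR186W (0.93 ± 0.08 against 0.91 for the first harmonic), YDL218W (0.74 ± 0.09 against 0.66) and YGL262W (0.68 ± 0.07 against 0.67). They were followed by the sulfiredoxin gene SRX1 (0.67 ± 0.08 against 0.66), YMR030W-A (0.66 ± 0.08 against 0.37) and the ABC transporter gene PDR15 (0.63 ± 0.06 against 0.54). Of these 6, YMR030W-A alone did not pass the test of the first harmonic (limma adjusted p = 0.13). Because of this asymmetry a fitted peak phase can lie away from the highest sample. The ribosome biogenesis list, for instance, had its fitted peak at 359.6° and its highest sample at 34.3°. The phase of the sample with the highest level is given beside the fitted peak for some of the gene lists.

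The series also allowed a check of whether levels returned after 1 cycle, since the 3 samples at the end have phase angles within 1.93° of those of the 3 at the start. COG1 (YGL223C), encoding a subunit of a Golgi tethering complex, was the only gene that passed: its mean log2 level was 10.25 in the first 3 samples and 9.23 in the last 3, a difference of -1.01 ± 0.07 (SE, limma adjusted p = 0.0386). Next in rank, none of them past the threshold, were the galactokinase gene GAL1 (0.59 ± 0.06), the histone H3 gene HHT2 (-0.71 ± 0.08), the splicing factor gene CWC15 (0.51 ± 0.06), the tropomyosin gene TPM2 (-0.55 ± 0.07) and CMR2 (-0.67 ± 0.09), each with a limma adjusted p of 0.141. At an unadjusted p under 0.05 the limma fit gave 752 genes, and the median absolute difference was 0.14. The call of COG1 was lost when any of the 6 samples was left out (0 genes in each case), whereas 1356 genes passed with the matched phase as a replicate block and 2393 with the deposited values. Deposited median log2 signals of the S. cerevisiae probe sets were 11.12, 10.99 and 11.09 in the first 3 samples. In the last 3 they were 10.72, 10.52 and 10.49, so the 2393 calls also hold a difference in array brightness. The 3 samples of each set are neighbours along the cycle, so their spread holds the course of the cycle itself. The comparison without the block leaves out the match in phase and counts that course as error. That only 1 gene passed it therefore does not show that levels returned after 1 cycle.

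For 31 gene lists fixed before the data were examined, the mean log2 level of the members was fitted in the same way. Each list is given with the range of its mean profile, its peak phase and the jackknife SE of both over the 32 samples. Every list passed a two-sided permutation test of its profile (100000 permutations of the phases), with adjusted p from 1.82e-05 to 0.0153; the smallest p that the permutations can give is 1e-05. Permuted phases ignore the autocorrelation between samples: after whitening, gluconeogenesis (adjusted p = 0.134), fatty acid synthesis (0.248), the iron regulon (0.37) and meiosis (0.0645) no longer passed. Leaving out blocks of 4 neighbouring samples in place of single samples gave larger errors, such as ± 22.1° in place of ± 8.4° for the peak of ribosome biogenesis. Members named as exceptions within a list were chosen after their values were seen.

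**Figure D2:**
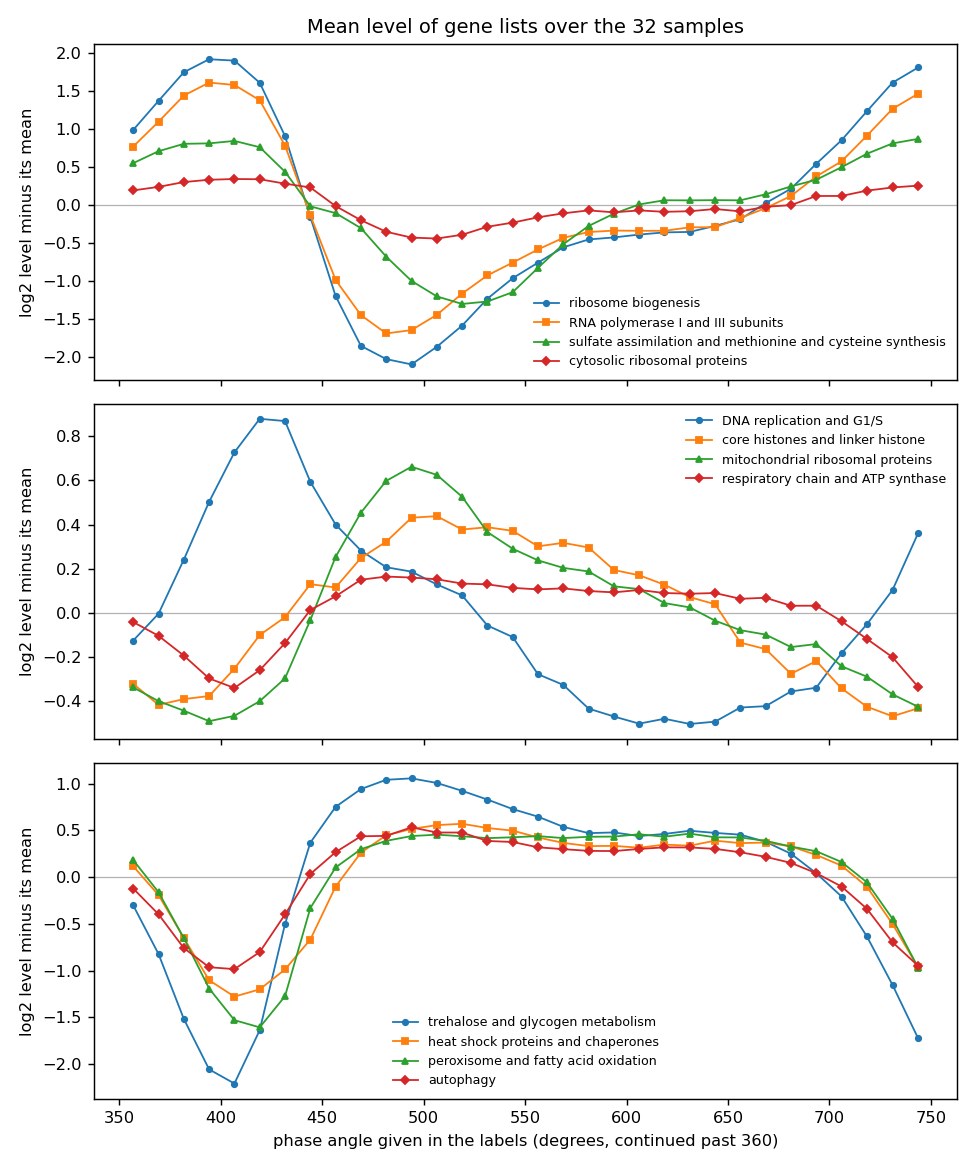
Mean log2 level of 12 gene lists, each minus its own mean, in the 32 samples against the phase angle of the labels in degrees; each point is 1 sample after quantile normalization. Ribosome biogenesis is highest at 34.3° and lowest at 134° while trehalose and glycogen metabolism is lowest at 46.8° and highest at 134°; the respiratory chain list, whose range is 0.34, has its fitted peak at 205° here and at 92.4° with poly-A scaling.

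Genes that build ribosomes showed the widest swing. Of 113 measured ribosome biogenesis genes, 112 varied with phase (112 adjusted over the list alone), all 112 by at least 2-fold and within 45° of the list's peak; ESF1 was the exception, with a range of 0.25. Their mean profile had a range of 2.85 ± 0.32 with a peak at 359.6° ± 8.4, and between its highest sample, at 34.3°, and its lowest, at 134°, it differed 16.3-fold. Beside DBP2, the nucleolar protein gene NSR1 (4.29 ± 0.43, peak at 352°) and RIX1 (4.21 ± 0.44, 3.6°) had the largest ranges. All 20 subunit genes of RNA polymerases I and III varied (20 adjusted over the list alone), with a list range of 2.23 ± 0.27 at 1.6° ± 9.1; RPA49, RPA43 and RPA12 of polymerase I led with 3.95 ± 0.47, 3.34 ± 0.42 and 3.12 ± 0.48. The cytosolic ribosomal protein genes moved less: 123 of 127 varied (123 adjusted over the list alone), 14 by at least 2-fold, with a list range of 0.54 ± 0.06 at 10.1° ± 8.9. RPL13A (1.91 ± 0.26), RPS26B (1.81 ± 0.21) and RPL22B (1.75 ± 0.29) had the largest ranges, and 24 of the members were read from probe sets that can match more than 1 gene. RPL4A, RPS23A, RPL40A and RPL10 did not pass, with ranges from 0.01 to 0.05.

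Translation genes outside the ribosome peaked in the same part of the cycle. Among cytosolic aminoacyl-tRNA synthetases, 18 of 19 varied (18 adjusted over the list alone), with a list range of 1.01 ± 0.10 at 21.8° ± 7.5 and the highest sample at 59.2°. The lysyl, tryptophanyl and methionyl synthetase genes KRS1 (2.37 ± 0.22), WRS1 (1.58 ± 0.22) and MES1 (1.55 ± 0.19) led, and GUS1 did not pass (0.06). All 31 genes of initiation and elongation factors varied (31 adjusted over the list alone), with a list range of 0.79 ± 0.09 at 13.1° ± 9.2. TIF4631, GCN3 and TIF3 had ranges of 2.00 ± 0.24, 1.63 ± 0.23 and 1.52 ± 0.17.

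Genes of amino acid and sulfur metabolism were high in the same part of the cycle. All 29 measured genes of sulfate assimilation and methionine and cysteine synthesis varied (29 adjusted over the list alone), 22 of them by at least 2-fold, with a list range of 1.70 ± 0.15 at 358° ± 5.3 and a 4.52-fold difference between the samples at 23.8° and 159°. Besides MUP1, MET8 (3.03 ± 0.26, peak at 2.4°) and MET16 (2.85 ± 0.23, 7.0°), enzymes of siroheme synthesis and sulfate reduction, led. Of 57 genes of other amino acid synthesis, 56 varied (56 adjusted over the list alone), with a list range of 0.80 ± 0.09 at 20.3° ± 7.4. The leucine, aromatic and serine synthesis genes LEU9 (2.92 ± 0.32), ARO7 (2.16 ± 0.22) and SER33 (1.91 ± 0.14) had the largest ranges; PRO3 did not pass (0.06).

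Mitochondrial ribosomal protein genes peaked after the cytosolic ones, by 165° in the fitted curves, 108° with 2 harmonics and 83.2° with poly-A scaling. All 73 varied (73 adjusted over the list alone) and all peaked within 45° of the list, whose range was 0.83 ± 0.09 at 175° ± 6.7, with the highest sample at 134° and the lowest at 34.3°. PET123 (1.31 ± 0.15), MRPL36 (1.10 ± 0.07) and MRPS12 (1.09 ± 0.11) led. Genes of the respiratory chain and ATP synthase mostly moved less than 2-fold: 36 of 37 varied (36 adjusted over the list alone), 1 by at least 2-fold. The list range was 0.34 ± 0.05 (percentile 97.3 of random lists) at 205° ± 8.7, a peak that became 92.4° with poly-A scaling. The exception above 2-fold was the NADH dehydrogenase gene NDI1 (1.10 ± 0.17, 193°); SDH2 (0.61 ± 0.11) and CYT1 (0.59 ± 0.08, on the other side of the cycle with poly-A scaling) followed, and QCR8 did not pass (0.39). In the tricarboxylic acid cycle list 10 of 11 varied (11 adjusted over the list alone), with a range of 0.44 ± 0.08 at 204° ± 11.8 that became 103° with poly-A scaling; it lay at percentile 90.5 of random lists. The 2-oxoglutarate dehydrogenase genes KGD2 (1.00 ± 0.16) and KGD1 (0.99 ± 0.15) and the succinyl-CoA ligase gene LSC2 (0.92 ± 0.14) led, and IDH1 did not pass (0.28). For mitochondrial protein import 24 of 26 varied (24 adjusted over the list alone), with a range of 0.26 ± 0.03 at 163° ± 7.1, or 90.9° with poly-A scaling. Of its members 17 peaked within 45° of the list and 3 over 90° from it. PAM17 (0.95 ± 0.09) and TOM22 (0.68 ± 0.09) peaked at 212° and 186° and PAM18 (0.85 ± 0.11) at 53.9°; TIM18 and TIM23 did not pass. Against random lists matched on expression, the import list lay at percentile 67.8.

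Storage carbohydrate genes were lowest near 47° and highest near 134°. All 18 genes of trehalose and glycogen metabolism varied (18 adjusted over the list alone), 16 by at least 2-fold, with a list range of 2.02 ± 0.31 at 199.7° ± 9.8. The level differed 9.61-fold between the lowest sample, at 46.8°, and the highest, at 134°. TSL1 of the trehalose synthase complex (3.39 ± 0.50) and the glycogen synthase genes GSY1 (2.99 ± 0.47) and GSY2 (2.82 ± 0.30) led. Genes of peroxisomes and fatty acid oxidation followed with a range of 1.37 ± 0.24 at 229° ± 8.4, with 32 of 33 varying (32 adjusted over the list alone) and PEX13 not passing (0.11). The peroxisomal catalase gene CTA1 (3.30 ± 0.50), the transporter gene PXA2 (3.23 ± 0.55) and the thiolase gene POT1 (2.94 ± 0.48) led. Gluconeogenesis, glyoxylate cycle and acetate use had 13 of 16 members varying (13 adjusted over the list alone) and a range of 0.58 ± 0.22 at 230.3° ± 14.7, which became 115° with poly-A scaling. Its adjusted p of 0.00893 in the permutation test became 0.134 after whitening. For this list the fitted curve explained only 0.249 of the variance, the highest sample lay at 96.6° and the maximum with 2 harmonics at 297°. In it the acetate transporter gene ADY2 (1.93 ± 0.41), the regulator gene CAT8 (1.55 ± 0.28) and the fructose-1,6-bisphosphatase gene FBP1 (1.55 ± 0.24) led, and YAT1, MLS1 and ALD4 did not pass.

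Among genes of glycolysis and hexose transport, those with the largest ranges peaked on both sides of the cycle. All 19 measured genes of glycolysis and ethanol formation varied (19 adjusted over the list alone), but the list range was 0.22 ± 0.04, at 246° ± 9.3, and its peak became 70.4° with poly-A scaling. With array medians it was 169.8° and the list no longer passed (adjusted p = 0.217). The hexokinase and glucokinase genes HXK1 (1.41 ± 0.27) and GLK1 (1.13 ± 0.20) peaked at 208° and 209°, whereas the pyruvate decarboxylase gene PDC6 (2.17 ± 0.10) peaked at 1.5°. Of 9 hexose transporter genes 8 varied (8 adjusted over the list alone), with a list range of 0.56 ± 0.14 at 249° ± 10.3. The list no longer passed with poly-A scaling (329° and adjusted p = 0.599) or without the 5 samples of lowest poly-A signal (0.0905). HXT4 (2.95 ± 0.29) peaked at 13.6° and HXT10 (2.68 ± 0.46) and HXT5 (2.17 ± 0.36) peaked at 215° and 225°; HXT1 did not pass (0.30). Against random lists of the same size and level, the glycolysis and hexose transporter lists lay at percentiles 63.5 and 88.1.

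Stress and protein turnover genes shared the trough near 47°. In the list of heat shock proteins and chaperones 26 of 27 varied (26 adjusted over the list alone), with a 2.39-fold range (jackknife SE 0.20 on the log2 scale) at 224° ± 8.7. HSP30, the aggregation factor gene BTN2 (2.62 ± 0.41) and SSE2 (2.59 ± 0.40) led, and SSE1 did not pass (0.11). Oxidative stress defence had 22 of 23 members varying (22 adjusted over the list alone) and a range of 0.80 ± 0.10 at 226° ± 7.2 (164° with poly-A scaling), led by CTT1, GPX1 (2.56 ± 0.33) and PRX1 (1.80 ± 0.26); SOD1 did not pass (0.11). All 23 autophagy genes varied (23 adjusted over the list alone), with a range of 1.06 ± 0.15 at 206° ± 8.5; ATG7 (2.29 ± 0.35), ATG14 (2.01 ± 0.26) and ATG3 (1.68 ± 0.21) led. For the vacuolar proteases 8 of 9 varied (8 adjusted over the list alone), with a range of 0.70 ± 0.11 at 218° ± 9.4 (137° with poly-A scaling), led by APE1 (1.36 ± 0.22), PRC1 (1.12 ± 0.15) and YSP3 (0.78 ± 0.13), and CPS1 did not pass (0.07). The proteasome list had 33 of 34 members varying (34 adjusted over the list alone), none by at least 2-fold, and a range of 0.47 ± 0.06 at 216° ± 6.7, which became 109° with poly-A scaling. RPN4, which encodes its transcriptional activator (0.88 ± 0.14), the assembly factor gene UMP1 (0.88 ± 0.09) and PRE3 (0.67 ± 0.08) led, and SCL1 did not pass (0.15).

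Cell cycle genes were spread around the oscillation. In the DNA replication and G1/S list 42 of 45 genes varied (42 adjusted over the list alone), 29 by at least 2-fold, with a range of 1.14 ± 0.09 at 80.3° ± 2.8 and the highest sample at 59.2°. CLB6, the cyclin gene PCL1 (2.53 ± 0.14) and the cohesin gene MCD1 (2.43 ± 0.18) led; DPB11, CTF4 and SLD3 did not pass. All 8 histone genes varied (8 adjusted over the list alone), with a range of 0.80 ± 0.04 at 177° ± 2.7 (123° with poly-A scaling), led by HHT2 (1.22 ± 0.11), the linker histone gene HHO1 (1.04 ± 0.08) and HTB2 (0.99 ± 0.05). Of the G2/M list 19 of 22 varied (19 adjusted over the list alone), 2 by at least 2-fold, with a range of 0.31 ± 0.04 at 3.2° ± 8.3 (percentile 76.3 of random lists); KIN3 (1.16 ± 0.08) and the cytokinesis genes HOF1 (1.01 ± 0.10) and CHS2 (0.88 ± 0.09) led, and CLB2, HST3 and APC1 did not pass. All 23 M/G1 genes varied (23 adjusted over the list alone), with a range of 0.60 ± 0.06 at 137° ± 6.2, but their peaks were dispersed (resultant length 0.402). FAR1 (2.31 ± 0.17) peaked at 35.6°, PCL2 (2.25 ± 0.20) at 84.2° and the cell wall gene PIR1 (2.01 ± 0.06) at 138°.

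Lipid, metal and phosphate genes showed small list ranges with members on opposite sides of the cycle. For ergosterol synthesis 23 of 24 varied (23 adjusted over the list alone), with a range of 0.30 ± 0.04 at 286° ± 5.1, which became 54.1° with poly-A scaling and no longer passed with array medians (adjusted p = 0.0954); ERG4 (1.40 ± 0.10) peaked at 65.8° and the reductase genes HMG1 (1.18 ± 0.10) and HMG2 (1.06 ± 0.14) at 237° and 212°, and ERG26 did not pass (0.06). All 11 fatty acid synthesis genes varied (11 adjusted over the list alone), yet the list range was 0.08 ± 0.03 at 321° ± 18.4 (66.6° with poly-A scaling, 87.6° with array medians). Its adjusted p of 0.0153 became 0.248 after whitening. Among its members the elongase genes ELO2 (1.05 ± 0.14) and ELO3 (1.04 ± 0.15) peaked at 42.2° and 17.8° and ELO1 (0.69 ± 0.10) at 227°. The iron regulon had 19 of 22 members varying (19 adjusted over the list alone) and a range of 0.14 ± 0.04 at 212° ± 18.6 (64.0° with poly-A scaling), with an adjusted p of 0.00682 that became 0.37 after whitening. FET3 (1.51 ± 0.17) and ARN1 (1.21 ± 0.11) peaked at 36.6° and 14.6° and the heme oxygenase gene HMX1 (2.84-fold, SE 0.18 on the log2 scale) at 256°; FIT2, FRE3 and SMF3 did not pass. Of the phosphate regulon 14 of 15 varied (14 adjusted over the list alone), with a range of 0.25 ± 0.05 at 129° ± 7.9 (77.1° with poly-A scaling; 217° and no longer passing with the deposited values, adjusted p = 0.336); SPL2 (1.81 ± 0.26) peaked at 184°, PHM6 (1.53 ± 0.18) at 23.1° and PHM8 (1.43 ± 0.26) at 208°, and PHO84 did not pass (0.64). Meiosis and sporulation had 23 of 31 members varying (23 adjusted over the list alone) and a range of 0.33 ± 0.05 at 190.1° ± 15.7 (83.9° with poly-A scaling), with an adjusted p of 0.000149 that became 0.0645 after whitening; SPS4 (2.09 ± 0.16) peaked at 26.8°, IME2 (1.30 ± 0.15) at 162° and the dim MEK1 (1.45 ± 0.27) at 228°. Random lists of the same size and level reached larger ranges than these 5 lists in many draws: the percentiles were 78.4 for ergosterol, 5.97 for fatty acid synthesis, 31.9 for iron, 53.0 for phosphate and 66.6 for meiosis.

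**Figure D3:**
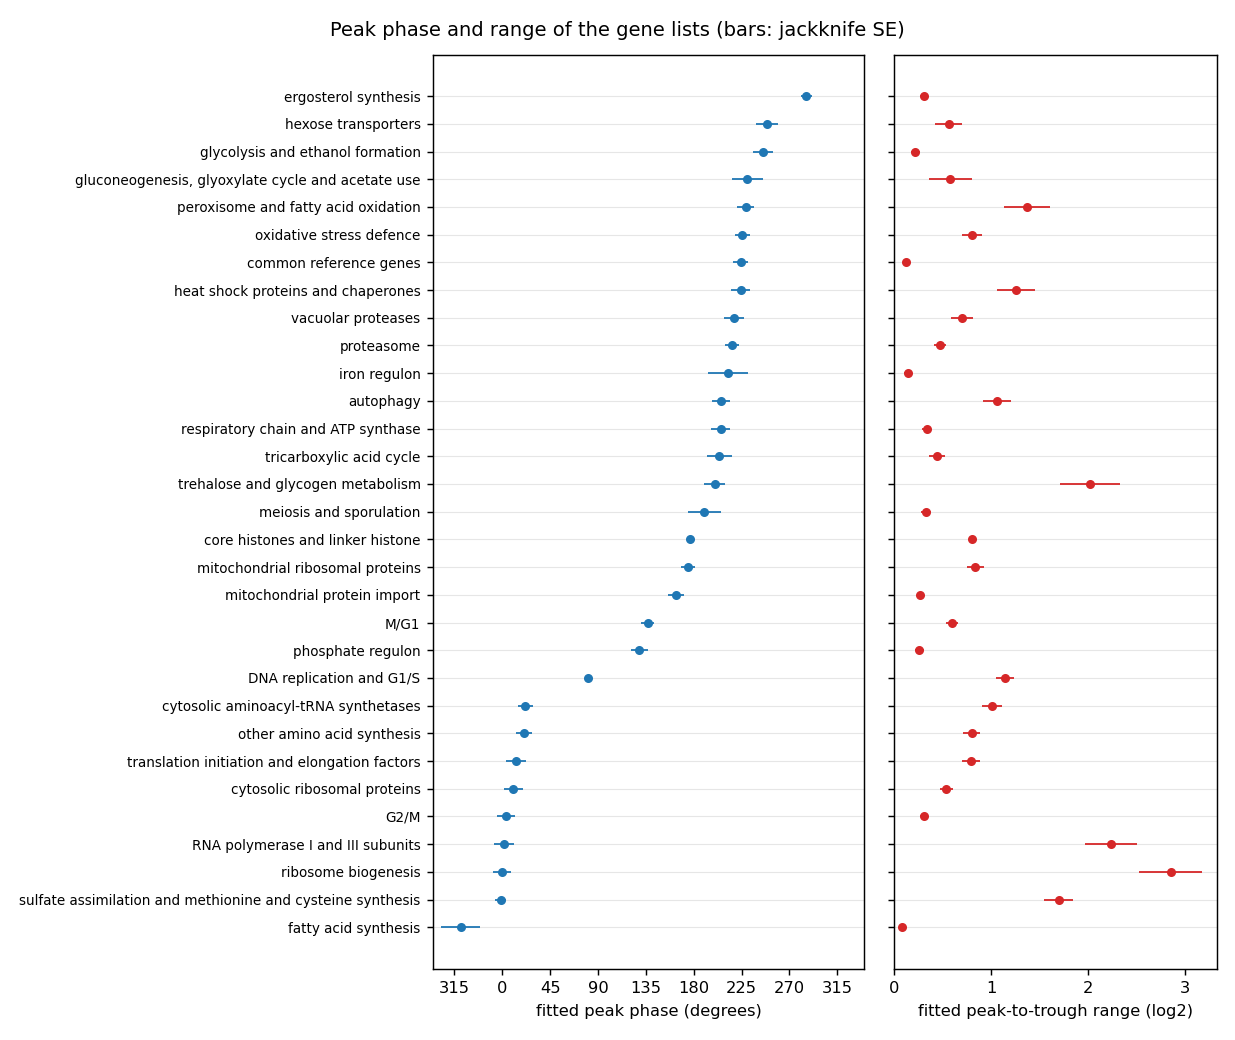
Fitted peak phase in degrees (left) and fitted peak-to-trough range on the log2 scale (right) of the mean profile of the 31 gene lists; bars are the jackknife SE over the 32 samples, after quantile normalization. Ribosome biogenesis has the largest range, 2.85; with poly-A scaling the peaks of 10 lists of small range move to the other side of the cycle, among them respiratory chain (92.4°), proteasome (109°), glycolysis (70.4°) and ergosterol (54.1°).

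Genes in common use as references for transcript levels had small ranges with quantile normalization. Of the 10, 8 varied with phase (7 adjusted over the list alone) and none by 2-fold; the list range was 0.12 ± 0.02 at 224° ± 7.2, which became 70.2° with poly-A scaling. The actin gene ACT1 (0.05 ± 0.03, limma adjusted p = 0.194) and TAF10 (0.10 ± 0.05, 0.129) did not pass. IPP1 (0.14 ± 0.03), CDC34 (0.18 ± 0.07), PDA1 (0.27 ± 0.03) and ALG9 (0.32 ± 0.06) had ranges below those of UBC6 (0.36 ± 0.05), TFC1 (0.38 ± 0.06), TRS65 (0.50 ± 0.11) and the tubulin gene TUB1 (0.64 ± 0.06). The range of the median over all genes was 0.17 with the deposited values and 0.62, with a peak at 61.9°, after poly-A scaling. Its difference between the highest and the lowest sample was 0.70 with the deposited values and 1.22 after poly-A scaling. Levels given here are therefore relative to the median gene. With poly-A scaling the order of these genes changed: ALG9 (0.54), CDC34 (0.49), PDA1 (0.62) and UBC6 (0.38) peaked on the other side of the cycle, as did TFC1 (0.25), which no longer passed (limma adjusted p = 0.211). ACT1 and TAF10 then varied, with ranges of 0.80 and 0.80.

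The order of the lists was compared for 11 pairs. Mitochondrial ribosomal protein genes peaked 165° ± 4.0 after cytosolic ribosomal protein genes (95% interval 156.5° to 173°, or 151.1° to 178.3° with blocks of 4 neighbouring samples left out, and 83.2° with poly-A scaling). Their difference from ribosome biogenesis was 175° ± 3.0 (124° with poly-A scaling, -172.8° with the deposited values). These 2 lists lay too near opposite sides of the cycle for the sign to give an order. Histone genes peaked 96.5° ± 3.4 after the DNA replication and G1/S list, which is 30.9 min, and mitochondrial ribosomal protein genes 94.5° ± 6.6 after it; with poly-A scaling these differences were 52.6° and 59.7°. The respiratory chain list peaked 30.4° ± 4.8 after mitochondrial ribosomal proteins, a direction that turned to -38.1° with poly-A scaling and -4.9° with array medians; with 2 harmonics the difference was 2° and no longer past the threshold. Trehalose and glycogen genes peaked before peroxisomal genes, at a difference of -29.1° ± 6.2 (-17° and no longer past the threshold with 2 harmonics), and ribosome biogenesis 131° ± 6.1 after the peroxisomal list, or -134° from the maxima of curves with 2 harmonics. The G2/M and histone lists differed by -174° ± 9.5, by -113° with 2 harmonics (no longer past the threshold) and by -86.6° with poly-A scaling. The interval of ribosome biogenesis minus cytosolic ribosomal proteins included 0 (-10.5°, 95% interval -21.7° to 0.689°). It excluded 0 with the deposited values (-22.6°), array medians (-36.2°), poly-A scaling (-40.4°), the running number (-10.7°) and 2 harmonics (-11°). That of cytosolic ribosomal proteins minus the sulfur list included 0 too (11.7°, -0.662° to 24.1°), but not with the deposited values (19.4°), array medians (30.5°) or poly-A scaling (30.0°). Heat shock genes peaked 8.27° ± 3.6 after the proteasome list (0.878° to 15.7°), an interval that included 0 (-9.38° to 25.9°) when blocks of 4 neighbouring samples were left out, and the difference was -2° with 2 harmonics and 83.5° with poly-A scaling.

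**Figure D4:**
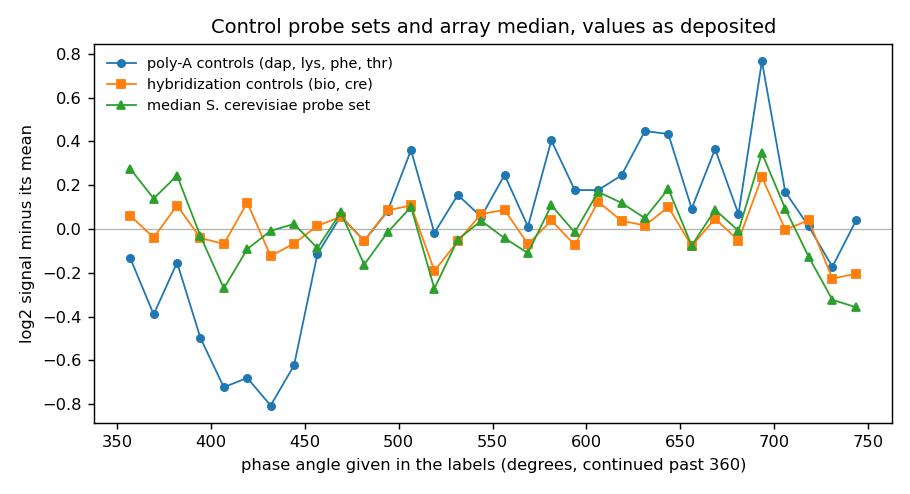
Mean log2 signal of the poly-A control probe sets and of the hybridization control probe sets, and median log2 signal of the S. cerevisiae probe sets, each minus its mean, in the 32 samples against the phase angle of the labels in degrees, with the deposited values. The poly-A controls are lowest in the 5 samples from 34.3° to 84.2°, by 0.79 below the others, where the hybridization controls differ by 0.04.

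The control transcripts on the arrays changed in the same samples in which ribosome biogenesis was highest (34.3°) and storage carbohydrate genes were lowest (46.8°). The poly-A control probe sets (dap, lys, phe and thr, 24 probe sets) had a mean log2 signal of 7.41 ± 0.12 (SD) in the 5 consecutive samples from 34.3° to 84.2° and of 8.20 ± 0.24 in the other 27, a 1.73-fold difference. The hybridization controls (bio and cre, 18 probe sets) had 10.65 ± 0.09 and 10.69 ± 0.11. Without those 5 samples, a check added after seeing the data, 4782 genes varied with phase (limma) and 1225 had at least 2-fold range.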

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

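The tests of drift, of profiles running ahead with their error between arrays, of hybridization brightness and of running number for the poly-A controls, and poly-A scaling and the omission of 5 samples, were chosen after the results were seen. Data outside the gene tests held a signal: of 251 probe sets without a gene name and brighter than the 99th percentile of the S. pombe probe sets, 220 varied with phase (limma adjusted p under 0.05; 221 at unadjusted p), 91 of them by at least 2-fold. Of the 1747 S. pombe probe sets, which served as background, 8 did (269 at unadjusted p). The 2 largest ranges among the unnamed probe sets, singled out after their values were seen, were 3.11 ± 0.35 with a peak at 258° and 3.04 ± 0.43 with a peak at 207°.

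Most genes varied over the sampled cycle. In 100 orders of the phases over the samples, only the real order, 1 of 100, gave as many varying genes (4910, against 625 in the highest other). The same held for genes with 2-fold range (1 of 100, with 1574 against 121) and with a second harmonic (1 of 100, with 4513 against 0). Such orders also break the autocorrelation between neighbouring samples, so any smooth course over time could give these counts. They therefore do not tell a cycle from another smooth course. A steady drift would separate the last from the first 3 samples, but the median difference was 0.123 of the fitted range, and the array running number beside both harmonics called 0 genes (limma adjusted p). No biological explanation was tested, since the design holds 1 culture and 1 condition.

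The last 3 samples lay ahead of the first 3 along the cycle by a slope of 5.71° over 1574 genes, beyond the 1.75° by which their labels differ. Resampling genes gave intervals above 0 in 6 of 8 windows of peak phase and below 0 in that from 270° to 315° (-37.6°, 5 genes), but these genes share the same 6 arrays. With the spread between sets of 3 neighbouring samples placed on the curve in the same way, which also holds misfit of the curve, the 95% interval was -11.2° to 22.6°, so profiles running ahead cannot be told apart from error between arrays. The shift did not vanish without quantile normalization: on the same arrays it was 13.1° ± 0.23 with the deposited values (9.34° ± 0.45 by the slope). Those errors are over genes and not arrays. Deposited array medians also fell, from 10.99 to 11.12 in the first 3 samples to 10.49 to 10.72 in the last 3. These values therefore do not settle whether quantile normalization was the source of the shift. Array running number explained 0.02 of the variance that the slope along the cycle did. For the comparison of first and last samples, 2 of 10 splits of the 6 samples gave as many genes as the real 1, with 1077 in the highest other; 10 splits are too few for a share under 0.05, and that split, which follows phase, points to a structure of the samples.

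The poly-A controls fell by 0.79 on the log2 scale in 5 consecutive samples. Hybridization or scanner brightness is argued against, since the hybridization controls changed by 0.0538 of that fall. The 9 arrays with neighbouring running numbers lay 3.51 SD above the 5. Since the 5 were picked as the lowest of all arrays, most of that gap was set beforehand, and it decides nothing about running number. The mean of these 9 was 8.25, against 8.20 ± 0.24 (SD) for all 27 other arrays, so arrays with neighbouring numbers were not low. Loss of 5-prime signal is argued against by a ratio of 1.09 between the 5-prime and 3-prime falls. A higher share of mRNA in the total RNA could produce equal falls of all 4 controls, and their range over the mean fall was 0.16. Less control RNA added to these preparations would give equal falls too and stays open, untested.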

How the results depend on the processing

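Poly-A scaling, array-median scaling, the omission of 5 samples and block errors were chosen after the data were seen. Over all alternatives the varying genes numbered 3601 to 5100, those with 2-fold range 1225 to 2202 and those with a second harmonic 3027 to 4561. Of the values for lists, 435 kept direction and side of the threshold, 19 lost the threshold without turning and 11 turned. For pairs the numbers were 143 the same, 8 weaker, 8 newly past and 6 turned, and for named genes 1905, 25, 13 and 7. A value that turned was counted as such even where it also lost the threshold, as gluconeogenesis, meiosis and TFC1 did with poly-A scaling. Array number and signal over the S. pombe background limit small ranges. Except where stated, the cause was not tested.

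The first and last 3 samples differed in 2393 genes with the deposited values and 1356 with matched phase as a block, against 1, and in 0 to 0 when each of the 6 samples was left out, which leaves fewer samples. The deposited values also hold the lower median signals of the last 3 arrays. With poly-A scaling the median over all genes itself peaked at 61.9°. List peaks then became 92.4° (respiratory chain), 102.9° (tricarboxylic acid cycle), 70.4° (glycolysis), 115.4° (gluconeogenesis, adjusted p 0.456), 109.1° (proteasome), 54.1° (ergosterol), 66.6° (fatty acid synthesis), 64° (iron), 83.9° (meiosis, 0.407), 70.2° (reference genes) and 329.2° (hexose transporters, 0.599). The genes ALG9, CDC34, CYT1, PDA1, TFC1, TPM2 and UBC6 turned, with ranges of 0.539, 0.493, 0.453, 0.616, 0.247 (adjusted p 0.211), 0.492 and 0.381. Differences became 83.2° (mitochondrial minus cytosolic ribosomal proteins), -40.4° (ribosome biogenesis minus cytosolic ribosomal proteins), -38.1° (respiratory chain minus mitochondrial ribosomal proteins), 30° (cytosolic ribosomal proteins minus sulfur) and -86.6° (G2/M minus histones). With array medians the peaks were 169.8° (glycolysis, 0.217), 286.2° (ergosterol, 0.0954) and 87.6° (fatty acid synthesis), and the same differences -36.2° (ribosome biogenesis), -4.9° (respiratory chain) and 30.5° (sulfur). With the deposited values they were 347° (fatty acid synthesis, 0.504), 217.2° (phosphate, 0.336), -22.6° (ribosome biogenesis) and 19.4° (sulfur).

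Whitening gave 227.2° (gluconeogenesis, 0.134), 324.4° (fatty acid synthesis, 0.248), 210.3° (iron, 0.37), 189° (meiosis, 0.0645) and 6.6° for heat shock minus proteasome. Odd time points gave 233.3° (gluconeogenesis, 0.167), 316.7° (fatty acid synthesis, 0.154), 216.6° (iron, 0.125) and 9° (heat shock minus proteasome), and even ones 227.5° (0.109), 325° (0.164), 207.3° (0.0926) and 7.6°, with fewer samples in each. Linear time gave 7.6° for the same difference, and the running number -10.7° for ribosome biogenesis minus cytosolic ribosomal proteins. Members scaled to SD 1 gave 237.9° (gluconeogenesis, 0.0674). Without the 5 samples of lowest poly-A signal the values were 220.9° (gluconeogenesis, 0.221), 249.5° (hexose transporters, 0.0905), 200.9° (iron, 0.0871) and 3° (heat shock minus proteasome). With 2 harmonics, which place the maximum of an asymmetric curve, differences were -11° (ribosome biogenesis minus cytosolic ribosomal proteins), 2° (respiratory chain minus mitochondrial ribosomal proteins), -113° (G2/M minus histones), -2° (heat shock minus proteasome), -17° (trehalose minus peroxisome) and -134° (ribosome biogenesis minus peroxisome). Those of 2°, -113° and -17° were no longer past the threshold.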

Other observations

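All values in this part were chosen after they were seen. Genes of allantoin use (DAL) and of purine synthesis (ADE), outside the fixed lists, moved as groups. The 9 measured DAL genes varied, 7 by at least 2-fold, with a mean range of 1.55 ± 0.16 and a peak at 36.1° ± 5.2 (adjusted p = 0.00448 against 10000 random lists). DAL1, the allantoinase gene, had 2.98 ± 0.27. DAL82 (0.26) was the exception in phase, at 136°, and DAL81 had an equally small range (0.26, at 6.1°). The 10 ADE genes had a mean range of 0.89 ± 0.04 with a peak at 60.1° ± 2.6 (adjusted p = 0.0411), and ADE4, which encodes the entry enzyme of the pathway, had 1.83 ± 0.09 at 38.0°. ADE16 was the exception, with 0.58 at 229.6°. The tRNA methyltransferase genes (TRM, 15 of 15 varying) had a mean range of 1.99 ± 0.23 at 5.3° (adjusted p = 0.0028). Of 112 families of genes with a shared name and at least 6 members, 11 passed.

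In the M/G1 list, the replicative helicase genes MCM2 (1.16), MCM3 (1.02), MCM5 (0.91), MCM6 (0.89) and MCM7 (1.04) peaked between 11.3° and 43.9°, and the cyclin gene CLN3 (1.54) at 17.2°. The daughter cell separation genes DSE1 (1.49), DSE2 (1.27) and CTS1 (0.96) peaked at 202°, 202° and 216°, and the inhibitor gene SIC1 (1.41) and EGT2 (1.75) at 153° and 163°. No test compared these members.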
